A study of Sus scrofa with 226 samples.

How the data were processed

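The data are gene counts and patch-clamp recordings of 226 single neurons from dorsal root ganglia of 10 wild-type pigs, grouped by the age of the animal and the day in culture given in the sample titles, with 124 cells at 1 day, 78 at 2 days and 24 at 3 days. Per the labels' protocols, the recording pipette was withdrawn into lysis buffer, a second and larger pipette then took up the whole cell, and both were broken into one tube for Smart-Seq2. Cells were therefore picked one at a time, and no doublet caller was run. The submitters' processing notes name bcl2fastq 2.20. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, and no coordinates are printed. Smart-Seq2 reads carry no molecular identifiers and do not mark the strand, so counting error alone understates the spread, and reads of overlapping genes on opposite strands could not be told apart.

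The deposited gene table holds estimated counts for 30420 genes, made by the authors with a tool not named in the sources used here and not scaled to library size. Of its values above 0, 52.1% were not whole, and the totals differed between cells. The values were summed over cells and rounded to whole numbers before any count test. Of the 30420 identifiers 14867 were paired with a symbol, and these took a median of 79.3% of a cell's counts. NEFH, CALCA and MRGPRD had no identifier paired with them and have no value here. The deposited cell table holds other values, one per cell and parameter, with no units stated. It has 420 columns, of which 46 recorded parameters measured in at least 70% of the cells were used. Of these 2 were exact copies of others and were tested all the same, so the 46 parameters held 44 different ones. It also names the animal of each cell. Its 269 lines include 43 that belong to no sample used here. Age and day in the cell table differed from the sample titles in 0 cells.

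Cells needed at least 1000 genes with a read, and all 226 passed. The mitochondrial share of counts had a median of 4.24%. Total counts ran from 109726 to 5506278, and the sums compared between classes from 957258 to 35190500. Cell numbers fell into 6 runs of 48 consecutive numbers, taken here as plates by inference, and most animals lay within 1 run.

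No file gave cell types, so cells were clustered with the Leiden method of scanpy 1.11.5 at a resolution of 0.5. The input was the natural log of CPM divided by a constant, plus 1, standardised per gene. It held 2000 variable genes, reduced to 15 principal components, with 10 neighbours per cell. Markers were compared on log2 CPM values with a pseudocount of 1. Variable genes were restricted to identifiers with a symbol, and genes were not centred by animal. These settings were chosen after several exploratory clusterings had been seen. A cluster was named when at least 3 markers of one class, fixed before the data were examined, were at least 0.5 higher on the log2 scale than in the other cells and its 10 leading genes did not go against the name. That threshold and the handling of rival names were set and revised after the clusters had been seen and before any class was compared. The 3 clusters that stayed unnamed held 27, 30 and 18 cells.

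A gene that helped to build a cluster would differ between clusters by construction. The genes were therefore divided at random (seed 1) into 2 sets, and cells were clustered on 1000 variable genes of each set. Each gene was tested in classes built from the set it was not in. This scheme was chosen after the data had been seen. The recorded values, which took no part in the clustering, were compared between classes from all variable genes.

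Counts were summed per animal and class (at least 2 cells, 17 sums, 7 animals with both classes) or per animal and day (at least 3 cells, 20 sums). Sums were tested with edgeR 4.0.16 under R 4.3.3, using TMM scaling, filterByExpr, the quasi-likelihood test with the animal as a block, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 3 days of culture were fitted together. Animals appear on both sides of these comparisons, so the animal itself pairs the samples. Age was tested as a slope per week over 9 sums at 1 day in culture. Log2 CPM values shown for sums use a prior count of 2. With 1 OSMR SST C-fibre-like and 1 peptidergic C-fibre-like class, the comparison between cell types and that of the OSMR SST type with other C-fibres were the same contrast. The planned comparison of A-fibre with C-fibre types was not made because no cluster could be named as A-fibre. NEFH, one of the fixed A-fibre markers, had no value and could not count towards such a name.

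The 26 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists with at least 5 tested members. Named genes were, by a rule fixed at the same time, the 8 with the highest and the 8 with the lowest log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM over 4, a symbol and the same direction in all but at most 1 animal, then the 2 genes with the smallest p of each called list, and 10 genes given whatever the test showed. PROM1 and the further list members named in the text fall outside it and were chosen after their values were seen. Some genes that the rule or the further choice selected, and a test of glial RNA made after the results that rested on one of them, are not reported here. For recorded values the rule took the 8 parameters with the smallest p, and for pairs the 5 highest and 5 lowest mean rho. Further parameters named in the text, such as diameter, rheobase and input resistance, fall outside that rule and were chosen after their values were seen.

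Recorded values were averaged per animal and side, and the differences were tested with an exact two-sided sign-flip permutation test over animals. Channel genes were set against parameters by Spearman's rho across the cells of each animal with at least 6 cells, and the mean rho was tested the same way. In peptidergic C-fibre-like cells alone 0 of 2562 pairs passed, with 135 at an unadjusted p under 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

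The tests were tried on simulated data with known answers. For edgeR, changes were put only into genes with a log2 CPM over 4, so recovery among genes below that is not known. With age, the fold change was spread over the whole range of ages. In the class comparison, run on 21097 genes, edgeR recovered 34.3% of genes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 8-fold. The same shares were 22.4%, 82.1% and 98.5% between 2 and 1 days, 2.99%, 55.2% and 84.8% between 3 and 1 days, and 1.49%, 43.3% and 95.5% with age. The sign-flip test recovered 15 of 15 parameters shifted by 1.5 SD, with 1 false call among 31. It recovered 0 of 20 gene and parameter pairs simulated with a correlation of about 0.8. A count of 0 pairs thus carries no information on relations of that strength. The simulated values were drawn independently for each cell, with no difference between animals, no missing values and no upper limit. Recovery in the recorded values may therefore differ.

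The alternatives fixed before the data were examined were size factors of DESeq2 in place of TMM, no filter, the Wald test of DESeq2 1.42.0, limma on means of single cells, at least 3000 genes per cell, at least 5 cells or 1 cell per sum, no block, days 1 and 2 only, medians, permutations of cell labels, Pearson's r, animals with at least 10 cells, a pseudocount of 10, and each animal left out in turn. Added after the data had been seen were at least 8000 genes per cell, another resolution, centring by animal, classes from all variable genes, thinned sums, sums per class and day, the run in the block, sums without clusters 3 and 6, recorded values at 1 day only or adjusted for capacitance or diameter, peptidergic C-fibre-like cells only, copied parameters left out, and lists without the naming markers. Classes were also swapped within animals, and days and ages permuted. These swaps were first run in larger number and then limited to 40 for run time.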

Results

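Single cultured neurons of the pig dorsal root ganglion, the cluster of sensory nerve cell bodies beside the spinal cord, were first recorded with a patch pipette and then collected one by one for sequencing, an approach known as Patch-seq. Libraries were made with Smart-Seq2, which amplifies full-length cDNA of one cell and carries no molecular identifiers. The neurons came from 10 animals and were recorded after 1, 2 or 3 days in culture. There were 78 neurons of 9 animals at 2 days and 24 neurons of 3 animals at 3 days, and all others, from 10 animals, were taken at 1 day. The animals were 11, 12, 14, 15, 17, 18 or 20 weeks old, which together with the day of culture made 16 groups of 2 to 38 cells. The total count per cell ran from 109726 to 5506278 with a median of 740524.5. The median total was 772789 at 1 day, 699993 at 2 days and 804739 at 3 days. By animal, the median total ran from 419349 in animal 5 to 2370770 in animal 3. A cell had reads for 3023 to 20463 genes, with a median of 13379.5. No 2 cells held identical values, and the highest correlation between 2 cells was 0.914 against a median of 0.713. The animal was the replicate in the main tests, and for these cells were averaged or summed within animals.

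The neurons fell into 6 clusters, and 2 classes of C-fibre neurons, the slowly conducting sensory neurons that include most nociceptors, could be named from markers. OSMR SST C-fibre-like cells were 51 neurons of 10 animals and carried OSMR and IL31RA, subunits of cytokine receptors, with SST and NPPB, which encode the peptides somatostatin and brain natriuretic peptide. Peptidergic C-fibre-like cells were 100 neurons in 2 clusters of 47 and 53 cells. Both carried TAC1, the precursor of substance P, and ADCYAP1, the precursor of the peptide PACAP. Some markers were shared between the classes. SST and NPPB were also raised in the peptidergic C-fibre-like cluster of 53 cells, and TAC1 in the OSMR SST C-fibre-like cluster. The stress genes NUPR1 and CDKN1A were among the leading genes of these 2 clusters. Cluster 2, with 27 neurons of 8 animals, was led by PCP4, PLCD4, ENO2 and the cold-gated channel gene TRPM8 and stayed unnamed. Cluster 3, with 30 neurons, had a median of 9758 genes per cell and no marker of any class. Cluster 6, with 18 neurons, was led by macrophage genes such as CTSS, TYROBP and C1QC. No cluster could be named as A-fibre neurons, so A-fibre and C-fibre neurons were not compared. This does not show that such neurons were absent. The A-fibre marker NEFH had no value here, and cluster 2 carried the A-fibre markers NTRK2, NTRK3 and SCN1A beside markers of other classes. The classes rest on clusters made here, so shares and differences may not match those of another naming of the same cells.

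The first comparison asked which genes differ between the OSMR SST C-fibre-like and the peptidergic C-fibre-like neurons. The question follows from the stated aim of finding markers of mechano-insensitive C-fibres. Neurons of unnamed clusters took no part. Whether a gene sets the OSMR SST C-fibre-like class apart from them, or rather marks the peptidergic C-fibre-like class, was not tested. OSMR (ENSSSCG00000016851) was 35.4-fold higher in these neurons than in peptidergic C-fibre-like neurons, with 8.47 ± 0.47 log2 CPM (counts scaled to a fixed library size, SD, n = 8 sums) against 2.87 ± 1.57 (n = 9). GABRA5, a subunit of the GABA-A receptor, was higher by 5.30 ± 0.44 on the log2 scale (SE), and IL31RA by 4.71 ± 0.28. ADCYAP1 was 239-fold lower, at 3.43 ± 1.89 against 11.18 ± 0.34 log2 CPM. SCN11A, the gene of the sodium channel Nav1.9, was higher by 3.00 ± 0.25, at 9.51 ± 0.22 against 6.59 ± 0.68. GAL, which encodes the peptide galanin, differed by -3.70 ± 0.21 on the log2 scale, and GAP43, a growth cone protein, by -1.75 ± 0.21.

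Of 22514 genes tested with edgeR, 1899 differed at an adjusted p under 0.05, 678 of them higher and 1221 lower in OSMR SST C-fibre-like neurons. Among called genes with a symbol, a mean log2 CPM over 4 and the same direction in all but at most 1 animal, others with large higher values were GNA14 (5.00 ± 0.45 on the log2 scale), DIRAS3 (4.55 ± 0.55), the transcription factor gene ETV1 (4.41 ± 0.41), TRARG1 (4.07 ± 0.43) and the amino acid transporter gene SLC6A20 (3.89 ± 0.26). Lower genes under the same limits included GNG8, a G protein subunit, at -6.51 ± 0.54, LTBP1 at -5.70 ± 0.51, the sodium pump subunit ATP1B2 at -5.62 ± 0.40 and FAIM2 at -5.11 ± 0.58. PROKR2, a prokineticin receptor, followed at -4.82 ± 0.37 and the receptor tyrosine kinase gene KIT at -4.81 ± 0.49. Each of these genes, OSMR, GABRA5, IL31RA and ADCYAP1 included, differed in the same direction in 7 of the 7 animals with both sums, and their adjusted p-values (edgeR) were between 9.78e-08 for IL31RA and 5.15e-05 for DIRAS3. In OSMR SST C-fibre-like sums some lower genes lay near the floor, such as GNG8, LTBP1 and FAIM2, with means of 1.04, 1.87 and 1.65 log2 CPM. The size of their differences is therefore uncertain. TAC1 was abundant in both classes, at 12.93 ± 0.26 and 12.52 ± 0.51 log2 CPM, with a difference of 0.25 ± 0.16 (edgeR adjusted p = 0.428). ATF3, a transcription factor induced by nerve injury, differed by -0.42 ± 0.32 (edgeR adjusted p = 0.541). OSMR, IL31RA, SST, NPPB, TRPA1, ADCYAP1 and TAC1 are among the markers by which the classes were named and are no independent evidence of a difference.

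The sodium channel list, which also holds FGF12, FGF13 and FGF14, lay higher in OSMR SST C-fibre-like neurons (camera adjusted p = 0.00459, adjusted p = 0.150 with an estimated correlation). Of 11 members measured, 5 were higher and 0 lower, namely SCN11A (3.00 ± 0.25), SCN2A (2.72 ± 0.33), SCN10A (1.33 ± 0.24), SCN9A (1.17 ± 0.18) and SCN7A (0.50 ± 0.15). SCN7A is also a member of the Schwann cell list. Adjusted over the sodium channel list alone the counts were also 5 and 0. Of 28 potassium channel genes, 9 were higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.373 with an estimated correlation). They included KCNA2 (5.64 ± 0.74), KCNG3 (4.09 ± 0.70), KCNK2 (2.29 ± 0.42) and the channel-interacting protein gene KCNIP4 (1.94 ± 0.18), while KCNQ5 was lower (-1.21 ± 0.33). KCNA2 had 0 counts in several peptidergic C-fibre-like sums, so its fold change depends on the prior count.

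The axotomy and regeneration list, genes that respond to injury of the axon, lay lower in OSMR SST C-fibre-like neurons. Of its 25 measured members 0 were higher and 8 lower (0 and 13 adjusted over the list alone). The 8 were GAL, GAP43, VGF (-2.71 ± 0.34), IL6ST (-2.31 ± 0.25), a signalling subunit shared by cytokine receptors, SMAD1 (-2.28 ± 0.29), FLRT3 (-1.67 ± 0.36), STMN4 (-1.55 ± 0.20) and GADD45A (-1.49 ± 0.27). This was the one list call of 7 that held with an estimated correlation, at an adjusted p = 0.0386, beside 8.63e-07 with the preset one. GAL is also a member of the peptidergic nociceptor list, and ATF3 and the remaining members did not pass over all genes.

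The list of OSMR SST C-fibre genes had 10 members higher and 1 lower of 16 (10 and 1 adjusted over the list alone, camera adjusted p = 1.17e-05, adjusted p = 0.0734 with an estimated correlation). The list holds markers by which the class was named, and without the naming markers of both classes 6 were higher and 1 lower of 12 (camera adjusted p = 0.0174, adjusted p = 0.277 with an estimated correlation). Beside the naming markers the higher members included JAK1, the kinase through which OSMR signals (2.95 ± 0.20), CYSLTR2, a leukotriene receptor (5.54 ± 0.47), and OTOA (3.83 ± 0.64), while the angiotensin receptor gene AGTR1 was lower (-2.99 ± 0.55). SST itself differed by 1.93 ± 0.23. The peptidergic nociceptor list had 2 higher and 8 lower of 14 (2 and 8 adjusted over the list alone, camera adjusted p = 7.15e-07, adjusted p = 0.0734 with an estimated correlation), and without the naming markers 2 higher and 5 lower of 10 (camera adjusted p = 0.00167, adjusted p = 0.188 with an estimated correlation). TRPA1 (-3.06 ± 0.30) and BDNF (-2.70 ± 0.41) were lower, whereas TRPV1, the capsaicin receptor (1.26 ± 0.24), and the opioid receptor gene OPRM1 (1.13 ± 0.26) were higher. The non-peptidergic C-fibre list had 6 higher and 1 lower of 13 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00498, adjusted p = 0.150 with an estimated correlation), with GRIK1 at 4.33 ± 0.77 and RET at 0.99 ± 0.16.

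The satellite glia list lay lower, with 0 higher and 3 lower of 13 (0 and 4 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.373 with an estimated correlation). The 3 were ATP1B2, the potassium channel gene KCNJ3 (-4.25 ± 0.88) and FBLN5 (-1.94 ± 0.52), whereas the abundant glial gene APOE differed by -0.70 ± 0.49. KCNJ3 had a mean of 0.19 log2 CPM in OSMR SST C-fibre-like sums, near the floor, so the size of its difference is uncertain. The mean log2 score over the satellite glia list holds ATP1B2, KCNJ3 and FBLN5, so it is no separate check. It was 2.38 ± 0.64 (SD, n = 10 animals) in OSMR SST C-fibre-like and 2.55 ± 0.73 in peptidergic C-fibre-like cells. The Schwann cell score went the other way, at 2.62 ± 0.56 against 2.16 ± 0.46. The mitochondrial share was 5.55% ± 3.18 against 3.60% ± 1.73, and cells had reads for 14155 ± 1916 against 12738 ± 1733 genes. The macrophage score was 1.88 ± 1.01 and 1.44 ± 0.53. The other 19 lists were not called by camera.

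**Figure D1:**
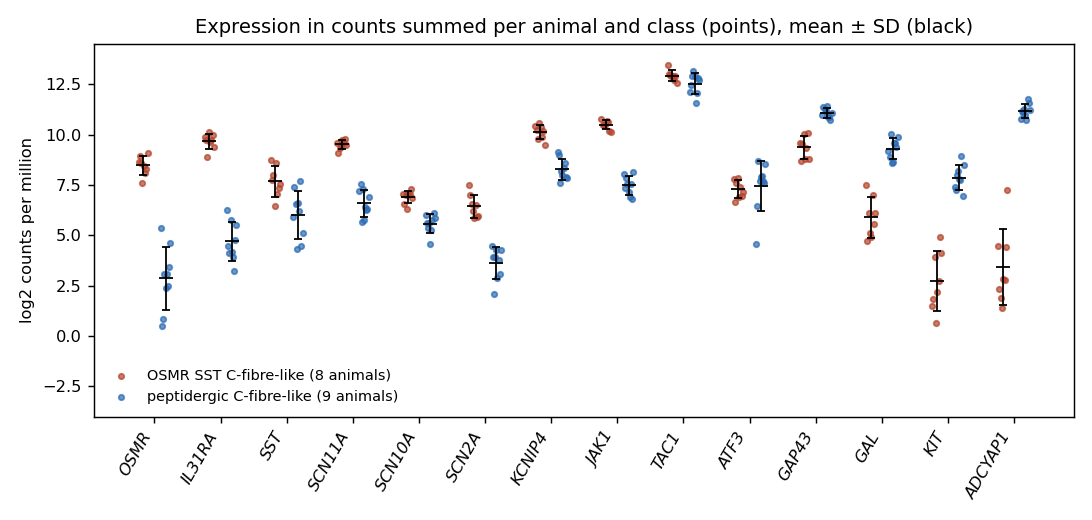
Log2 CPM of named genes in sums of OSMR SST C-fibre-like and peptidergic C-fibre-like cells, one point per animal, with bars for the mean and SD. OSMR had a mean of 8.47 in 8 sums of the first class and 2.87 in 9 sums of the second, and ADCYAP1 3.43 and 11.18.

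**Figure D2:**
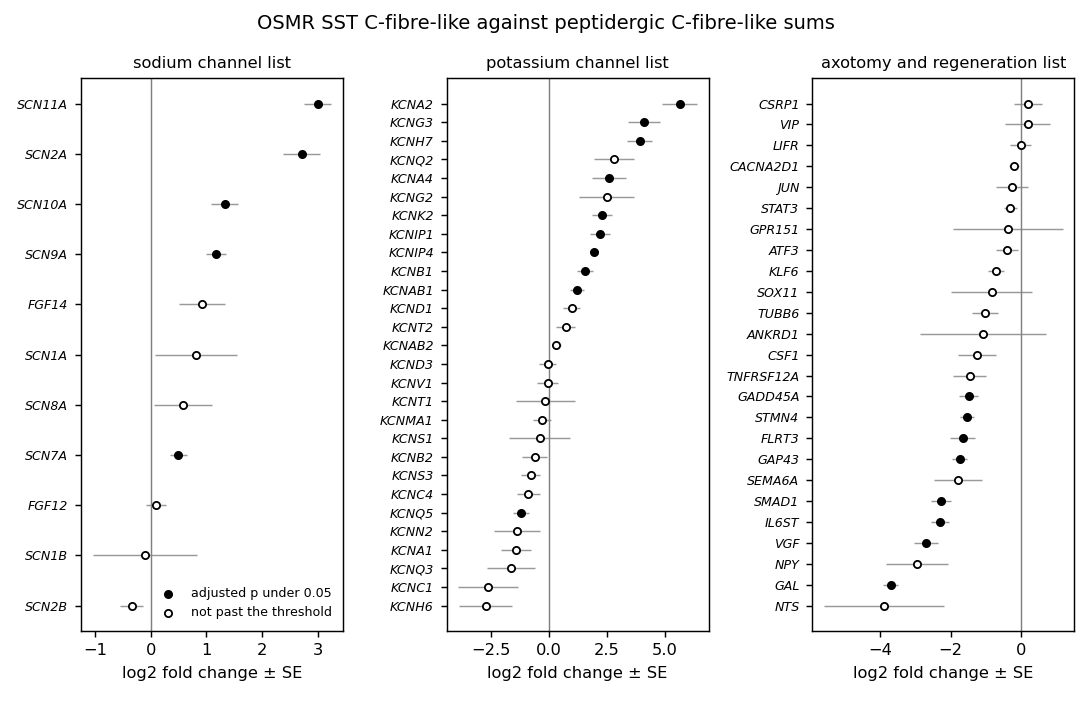
Log2 fold changes (OSMR SST C-fibre-like minus peptidergic C-fibre-like) with standard errors for the measured members of the sodium channel, potassium channel, and axotomy and regeneration lists. Of the 11 measured members of the sodium channel list 5 were higher and 0 lower, and of the 25 axotomy and regeneration genes 0 were higher and 8 lower.

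The test was edgeR's quasi-likelihood test on 17 sums with the animal as a block and Benjamini-Hochberg adjustment, and each gene was tested in classes built from the other random share of the genes. With size factors in place of TMM in the same fit 771 genes were higher and 1052 lower. The median log2 fold change of all genes was -0.09 with TMM, -0.02 with size factors and 0.07 with means of single cells. On those means limma, which changes the test and the unit as well as the scaling, called 884 genes higher and 611 lower.

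The second comparison asked whether the same classes differed in their recorded properties. OSMR SST C-fibre-like neurons were larger, with a diameter of 42.7 ± 3.00 (SD of animal means, n = 10 animals) against 34.4 ± 3.05 in peptidergic C-fibre-like neurons. Their cell capacitance, which grows with membrane area, was 117.8 ± 20.98 against 54.97 ± 13.89 and was higher in 10 of 10 animals. They gave lower values in the columns named for 4 to 100 Hz, which run from 0 to 20 and for which the table gives no definition. The 50 Hz value was 3.80 ± 1.80 against 14.4 ± 2.32, the 20 Hz value 9.11 ± 2.87 against 18.8 ± 1.45 and the 100 Hz value 2.23 ± 0.853 against 7.01 ± 1.49, each lower in 10 of 10 animals. Action potentials lasted longer, with a duration of 4.15 ± 0.637 against 2.96 ± 0.261, in 9 of 10 animals, and rheobase, the current needed to evoke one, was 232.9 ± 80.5 against 143.5 ± 53.9. The table states no units, so these values are compared only with each other.

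Of 46 recorded parameters 15 passed at an adjusted p under 0.05, 8 of them higher and 7 lower in OSMR SST C-fibre-like neurons, and 22 had an unadjusted p under 0.05. The exact two-sided sign-flip test over animals gave p = 0.00195 (adjusted p = 0.0180) for capacitance and for the 20, 50 and 100 Hz values, the smallest p that 10 animals can give. The 10 Hz value (13.4 ± 4.35 against 19.6 ± 1.02) and the 4 Hz value (14.6 ± 3.96 against 19.6 ± 0.818) were lower in 9 animals and higher in 0 (exact p = 0.00391, adjusted p = 0.0180). Diameter, action potential duration and the parameter named HS_Threshold (382 ± 98.4 against 256 ± 80.4) each had the same exact p and were higher in 9 of 10 animals. Input resistance, listed in 2 versions, was lower, at 0.120 ± 0.0537 against 0.261 ± 0.0929 in the newer one. With the 8 animals that had both classes at 1 day in culture, 0 parameters passed the adjustment over 46 (exact sign-flip test). The smallest p that 8 animals can give, 0.00781, was reached by 6 parameters, where 8 would have been enough for a pass. There the 50 Hz value differed by -12.5 ± 3.22 and capacitance by 83.5 ± 21.5.

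**Figure D3:**
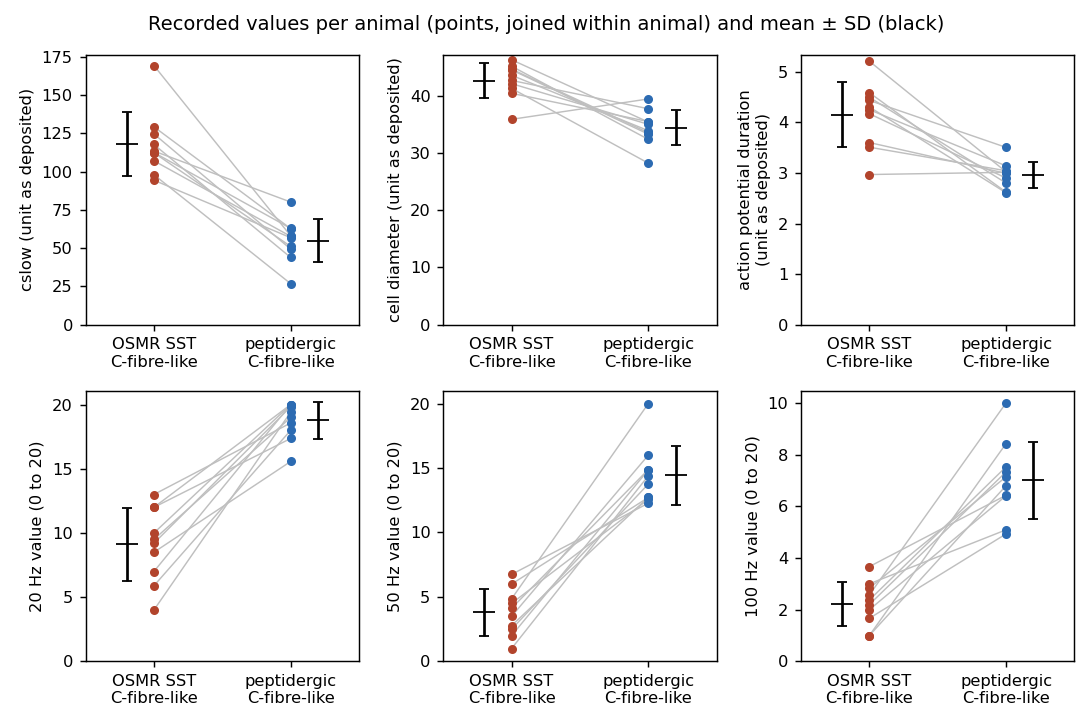
Recorded values of the parameters with the smallest p between classes, as animal means of OSMR SST C-fibre-like and peptidergic C-fibre-like neurons joined by a line per animal, with the mean and SD; the table states no units. Capacitance was higher in 10 of 10 animals, with means of 117.8 and 54.97, and the 50 Hz value lower in 10 of 10, with means of 3.80 and 14.4.

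The third comparison set ion channel genes against the recorded values of the same cells. Across the cells of each animal, neurons with more KCNG3 had lower 20 Hz values, with a mean Spearman's rho of -0.531 ± 0.289 (SD, n = 10 animals), and so did neurons with more SCN11A (-0.507 ± 0.141) and more ANO3 (-0.493 ± 0.126). TMC3, a transmembrane channel-like gene, had a mean rho of -0.508 ± 0.136 with the 100 Hz value and -0.501 ± 0.154 with the 50 Hz value. Each of these 5 pairs was negative in 10 of 10 animals, with p = 0.00195 by the exact sign-flip test, the smallest possible, and an adjusted p = 0.0652. The highest mean rho values were those of KCNIP4 (0.498 ± 0.208), TMC3 (0.490 ± 0.142) and ANO3 (0.480 ± 0.114) with the parameter named ADS_RT_ABS1 and of KCNIP4 (0.482 ± 0.205) and ANO3 (0.464 ± 0.139) with ADS_RT_ABS75, positive in 7 of 7 animals (exact p = 0.0156, adjusted p = 0.120).

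Of 2806 pairs of 61 genes and 46 parameters 0 passed by the exact sign-flip test, with 586 at an unadjusted p under 0.05. With Pearson's r 0 passed as well, with 566 at an unadjusted p under 0.05, and KCNG3 had a mean r of -0.512 with the 20 Hz value. The smallest possible p was reached by 84 pairs, where 110 would have been enough for a pass. The cells fall into classes that differ in both measures. Within the peptidergic C-fibre-like cells alone TMC3 had a mean rho of -0.0270 with the 100 Hz value and -0.0508 with the 50 Hz value. With ADS_RT_ABS1 the mean rho was -0.0439 for KCNIP4, 0.0521 for TMC3 and 0.236 for ANO3. With ADS_RT_ABS75 it was -0.0988 for KCNIP4 and 0.191 for ANO3. In these cells 0 of 2562 pairs passed by the exact sign-flip test. With the 20 Hz value the mean rho was -0.220 for SCN11A, -0.210 for ANO3 and -0.106 for KCNG3. These say little, since 85.9% of these cells sat at the largest 20 Hz value.

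The fourth comparison asked what changed with time in culture. Between 1 and 2 days 0 of the genes named beforehand passed, with a difference of 0.41 ± 0.34 for OSMR (SE, log2 scale), 0.17 ± 0.24 for SST, -0.05 ± 0.13 for TAC1, -0.31 ± 0.42 for SCN10A, 0.09 ± 0.20 for SCN11A, -0.03 ± 0.20 for GAP43 and 0.43 ± 0.36 for ATF3. GAL differed by -1.63 ± 0.63 and was lower in 5 of 7 animals. By edgeR 0 of 23077 genes passed, while DESeq2 called 42 genes (25 higher, 17 lower) and limma 0. In edgeR 831 genes had an unadjusted p under 0.05, fewer than the 1153.85 that chance alone gives on average. Among genes with a log2 CPM over 4, the same test recovered 82.1% of those simulated with a 4-fold change in this comparison. It recovered 22.4% of those with a 2-fold change, and genes below that level were not simulated with a change. Camera called 3 lists lower at 2 days, with 0 members passing over all genes and 0 adjusted over the list alone in each. They were cholesterol synthesis (median -0.31, adjusted p = 0.00127, adjusted p = 0.865 with an estimated correlation), transduction channels (median -0.50, adjusted p = 0.00680, adjusted p = 0.759 with an estimated correlation) and satellite glia (median -0.46, adjusted p = 0.0445, adjusted p = 0.865 with an estimated correlation). FDPS, an enzyme of the cholesterol pathway, was at -0.47 ± 0.16 and HMGCS1 at -0.49 ± 0.21, TRPV1 at -0.75 ± 0.31, and the glial genes APOE at -1.32 ± 0.50 and BCAN at -1.60 ± 0.95.

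Between 1 and 3 days PROM1, which encodes the membrane protein prominin-1, rose by 5.81 ± 0.77 on the log2 scale (edgeR adjusted p = 0.0475), from -0.48 ± 0.64 log2 CPM (SD, n = 9 animals) to 4.38 ± 0.67 (n = 3), and did so in 3 of 3 animals. It was the 1 gene of 23077 that passed and is named here after its value was seen. At an unadjusted p under 0.05 there were 2706 genes, where chance alone gives 1153.85 on average. Splits with days swapped within animals gave up to 1650. DESeq2 called 746 genes (354 higher, 392 lower) and limma 1 gene other than PROM1. The call of PROM1 was lost with limma, without animal 2, 4, 5, 7, 9 or 10, without clusters 3 and 6, with sums per class and with the run of cell numbers in the block, and without a block for animals 34 genes passed. Of the other named genes SCN10A was at -1.81 ± 0.63, SCN11A at -1.01 ± 0.29, OSMR at -0.64 ± 0.47 and GAL at -1.29 ± 0.88, and SST, TAC1, ATF3 and GAP43 at 0.04 ± 0.34, -0.16 ± 0.18, 0.51 ± 0.49 and -0.11 ± 0.28, none of which passed (edgeR adjusted p of 0.294 or more).

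Camera called 4 lists higher at 3 days, with 0 members passing over all genes. They were ribosomal protein, oxidative phosphorylation, heat shock and unfolded protein, and A-fibre and LTMR, with a camera adjusted p of 2.15e-06, 0.000104, 0.0442 and 0.0205, and all 4 calls were lost with an estimated correlation (adjusted p = 0.549, 0.549, 0.817 and 0.549 with an estimated correlation). The ribosomal protein list had a median of 0.55, with 7 of 17 higher adjusted over the list alone, such as RPL23 (0.88 ± 0.25) and RPS20 (0.85 ± 0.24). The oxidative phosphorylation list, genes of the mitochondrial respiratory chain, had a median of 0.54, with 9 of 19 higher adjusted over the list alone, such as CYCS (0.79 ± 0.21) and COX5B (0.66 ± 0.19). The heat shock and unfolded protein list had a median of 0.18, with CRYAB (2.90 ± 0.59) and HSPA8 (0.98 ± 0.19) the 2 of 15 higher adjusted over the list alone. The A-fibre and LTMR list (genes of large sensory neurons and low-threshold mechanoreceptors) had a median of 0.85, with the neurofilament gene NEFL (0.91 ± 0.25) the 1 of 17 higher adjusted over the list alone. Cells had reads for a mean of 11400 ± 1091 genes at 3 days (SD, n = 3 animals) and 13250 ± 2353 at 1 day (n = 10). The difference was not tested within animals. By age, the median number of genes per cell was 13529 at 1 day and 13250 at 3 days at 11 weeks. It was 17292.5 and 9755 at 14 weeks, and 14951 and 10476 at 18 weeks. At 11 and 18 weeks the cells at 1 day came from 2 animals and those at 3 days from 1. The median of all genes was -0.26 with TMM, -0.16 with size factors and -0.33 with means of single cells, and the 4 medians lay above each. Reads of ribosomal protein genes can be split with their many processed copies, so single members are uncertain. Cluster 2 made up 8.06% of the cells at 1 day and 37.5% at 3 days, 9 of 24 cells. These shares pool the cells of 10 animals at 1 day and of 3 animals at 3 days. They were not compared within animals or tested.

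Of the 46 recorded parameters 0 passed between 1 and 2 days by the exact sign-flip test over 9 animals, with 15 at an unadjusted p under 0.05 and a lowest adjusted p of 0.135. The parameter with the smallest p, Min_AHP, was -71.6 ± 1.70 at 2 days and -75.1 ± 3.08 at 1 day (exact p = 0.00781), higher in 8 of 9 animals. The parameter named TTP was 32.2 ± 9.94 against 51.9 ± 15.0 (exact p = 0.0117), lower in 8 of 9. The share of OSMR SST C-fibre-like cells was 20.6% ± 14.0 (SD, n = 7 animals) at 1 day and 20.9% ± 13.1 at 2 days (exact sign-flip p = 0.969), and that of peptidergic C-fibre-like cells 45.1% ± 15.9 and 44.5% ± 15.1 (exact sign-flip p = 0.984). Cells were picked for recording, so these are shares of the picked cells.

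The fifth comparison asked whether expression at 1 day changed with the age of the animal. By edgeR 0 of 19508 genes passed over 9 animals, while DESeq2 called 53 genes (36 higher, 17 lower with age) and limma 1. In edgeR 1233 genes had an unadjusted p under 0.05, where chance alone gives 975.4 on average and permuted ages gave up to 2229. Per week of age the named genes were at -0.18 ± 0.09 for OSMR, -0.24 ± 0.07 for SST, 0.25 ± 0.07 for ATF3, 0.15 ± 0.09 for GAL, -0.08 ± 0.05 for TAC1, -0.06 ± 0.07 for SCN11A, -0.02 ± 0.05 for GAP43 and -0.01 ± 0.07 for SCN10A. Camera called 4 lists, with 0 members passing over all genes, and each was lost with an estimated correlation (adjusted p = 0.752 with an estimated correlation for each). The macrophage and lymphocyte list lay higher with age (median 0.40 per week, adjusted p = 0.000907, 2 of 14 higher adjusted over the list alone), with the complement genes C1QC at 1.16 ± 0.29 and C1QA at 0.54 ± 0.17, and so did cholesterol synthesis (median 0.04, adjusted p = 0.0276, 0 of 20). C1QC and C1QA were near the floor, at a mean of 1.05 and 1.79 log2 CPM, and C1QC was a leading gene of cluster 6. The OSMR SST C-fibre list (median -0.08, adjusted p = 0.0179, 1 of 14 lower adjusted over the list alone) and oxidative phosphorylation (median -0.05, adjusted p = 0.0179, 0 of 19) lay lower. Animals of neighbouring ages were nested in the 6 runs of cell numbers, so age and run could not be told apart.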

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

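The tests of recorded values below were chosen after the class differences had been seen. Of 75 groups of 4 to 10 animal means, sums or cells, 4 held one value far from the nearest other, where chance gives 3.75. In animal 1 the peptidergic C-fibre-like class was 1 cell, with a 50 Hz value of 20.0, the largest the column holds, and the nearest other animal was at 16. In animal 2 the same class had a mean 10 Hz value of 16.9, with the nearest animal at 18.9, and a mean 4 Hz value of 17.6, with the nearest at 18.8. In animal 6 the 2 OSMR SST C-fibre-like neurons had a mean capacitance of 169.25, with the nearest animal at 129.3. Whether the class differences in recorded values changed with age, at or under 15 weeks against older, was tested for the 8 parameters with the smallest p, and the lowest permutation p was 0.233 (exact permutation of 4 older against 6 younger animals).

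OSMR SST C-fibre-like neurons had lower values at 20, 50 and 100 Hz and longer action potentials than peptidergic C-fibre-like neurons, and a larger capacitance, so capacitance is a candidate explanation for the other differences. With the slope on capacitance within animal and class taken out, the difference in action potential duration went from 1.19 to 1.06 and stayed positive in 9 of 10 animals (exact sign-flip p = 0.00391), which argues against capacitance as its cause. The 100 Hz difference went from -4.78 to -1.03 (exact sign-flip p = 0.127), which is what capacitance as the cause would give, although a p above the threshold does not show that no difference was left. The 50 Hz difference went from -10.6 to -2.85 (8 of 10 animals, exact sign-flip p = 0.0156), rheobase from 89.4 to 4.12 (5 of 10, p = 0.855) and input resistance from -0.140 to -0.0340 (7 of 10, p = 0.297). With the slope on diameter taken out instead, the 50 Hz difference went from -10.5 to -6.51 and the 100 Hz difference from -4.65 to -2.51, each in 10 of 10 animals (exact sign-flip p = 0.00195), rheobase from 91.2 to 18.9 (5 of 10, p = 0.492) and input resistance from -0.143 to -0.0348 (7 of 10, p = 0.328), so cell size as a cause stays open. The 20 Hz difference went from -9.67 to -3.12 with the slope on capacitance taken out and was -8.66 with that on diameter (each in 10 of 10 animals), but 85.9% of the peptidergic C-fibre-like cells sat at the largest value of that column, so both slopes are flattened and the explanation stays open. A different mix of culture days in the classes is argued against, since at 1 day alone the 50 Hz value differed by -12.5 (exact sign-flip p = 0.00781, the smallest possible).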

How the results depend on the processing

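All tests of swapped labels, and the alternatives with at least 8000 genes, other clusterings, class sums, runs, clusters left out, thinned sums, 1 day only, 1 class only, copied parameters left out and lists without naming markers, were chosen after seeing the data. Over 41 settings 1892 values were recomputed. The minimum of 3000 genes per cell removed no cell and tested nothing. The A-fibre alternatives were not run, as no A-fibre class was named. In the class comparison 609 values of 29 named genes were recomputed, of which 605 kept direction and side of the threshold, 3 passed it newly, 1 no longer passed and 0 reversed. The count of 1899 genes stayed between 1303 and 1887 with each animal left out and between 1495 and 2307 under the other settings except DESeq2, which called 3157 (1140 higher, 2017 lower), 1847 of them among the 1899. Thinned to the smallest sum, 75.6% of the 1899 genes were called again, which argues against depth as the cause. Of 40 splits with classes swapped within animals, the real one included, 1 called as many as 1899 genes. The highest other count was 2. Swapped splits carry the class difference on both sides, which widens the spread, so low counts there were likely beforehand. They do not test whether the clusters themselves arose by chance. For the counts of 0 genes at 2 days (all 40 splits as large, highest other 0) and with age (all 40 as large, highest other 22) the splits decide nothing, since no count is below 0. That 1 permuted order of ages called 22 genes points to a structure of the samples or to chance, which was not tested. The splits at 3 days were too few for a share under 0.05, with a real count of 1 and a highest other of 0.

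DESeq2 also called 42 genes at 2 days, 746 at 3 days and 53 with age, where edgeR called 0, 1 and 0, and limma called 1 with age and, at 3 days, 1 that edgeR did not call. At 3 days 3 genes passed without a filter, 3 with at least 5 cells per sum, and 0 without clusters 3 and 6, with class sums or with runs in the block. Without the replicate block for animals 34 passed (27 higher, 7 lower), GAL at 3 days turned to 0.18 and SCN11A at 2 days to -0.27. With each animal left out the count ran from 0 to 1 at 2 days (1 without animal 4) and from 0 to 1 at 3 days, where 0 passed without animal 4, 5, 7, 9 or 10. With an estimated correlation camera called 0, 0, 0 and 1 lists at 2 days, at 3 days, with age and between classes, and fry 0, 1, 0 and 13, where the preset correlation gave 3, 4, 4 and 7. Of the recorded parameters 23 passed between classes and 9 between days when cell labels were permuted, which counts cells as replicates, against 15 and 0. With 1 day only 0 passed, with 6 parameters at the smallest possible p of 0.00781, where 8 would have been enough for a pass. Without the 2 copied parameters 16 of 44 passed between classes and 0 of 44 between days. The cause of the other changes was not tested.

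The 44 values that reversed were of results that did not pass. With at least 5 cells per animal and day the share of peptidergic C-fibre-like cells changed by 1.87 and that of unnamed clusters by -7.83 percentage points. The share of OSMR SST C-fibre-like cells kept its sign there, at 5.96 points (exact sign-flip p = 0.438) against 0.345 in the main setting. At 2 days GAP43 turned to 0.0075 with DESeq2, 0.0075 with size factors, 0.10 with 5 cells per sum and 0.034 with 8000 genes, and ran from -0.18 to 0.17 with each animal left out. TAC1 turned to 0.030 with 5 cells per sum, 0.10 with class sums and 0.044 with runs, and ran from -0.13 to 0.035 with each animal left out. SCN11A turned to -0.76 with limma, -0.57 with class sums and -0.026 without clusters 3 and 6, and ran from -0.042 to 0.21 with each animal left out. OSMR turned to -0.36 with limma and -0.093 with class sums, and SST to -0.57 with class sums. At 3 days OSMR turned to 0.036 and ATF3 to -0.54 with limma, GAP43 to 0.40 with class sums, and SST to -0.081 with runs and -0.094 without clusters 3 and 6. With each animal left out GAP43 ran from -0.25 to 0.17 and SST from -0.31 to 0.27. With age, limma turned GAP43 to 0.17, OSMR to 0.063, SCN10A to 0.12, SCN11A to 0.073 and COX5A to 0.027, and SCN10A turned to 0.0070 without clusters 3 and 6. With each animal left out SCN10A ran from -0.080 to 0.081, SCN11A from -0.19 to 0.0060 and GAP43 from -0.035 to 0.018. In peptidergic C-fibre-like cells alone KCNIP4 turned to -0.0439 with ADS_RT_ABS1 and -0.0988 with ADS_RT_ABS75. The cause was not tested. Fold changes of genes near the floor, such as KCNA2, are uncertain, and most simulated changes of 2-fold were missed in each comparison.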

Other observations

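The test of read depth, given with the alternatives, and the tests of the ribosomal protein list below were written down before their results were seen. Neuropeptide genes split between the classes in both directions. Of 17 measured, 5 were higher and 5 lower in OSMR SST C-fibre-like neurons by edgeR (6 and 6 adjusted over the list alone), and camera did not call the list. Beside SST and NPPB, the gene of neuromedin B, NMB, was higher by 3.30 ± 0.22 on the log2 scale and the granin genes CHGA and CHGB by 1.58 ± 0.47 and 0.94 ± 0.21. PDYN, the precursor of dynorphin, was at -6.84 ± 0.50, beside ADCYAP1, GAL, VGF and BDNF on the lower side. Receptors of pain and itch mediators also went both ways, with 7 higher and 5 lower of 29 (8 and 6 adjusted over the list alone). CYSLTR2 was at 5.54 ± 0.47, the neuropeptide Y receptor genes NPY2R and NPY1R at 3.92 ± 0.67 and 1.61 ± 0.24, the prostaglandin receptor gene PTGER2 at 3.21 ± 0.66, the GABA-B subunit GABBR2 at 2.22 ± 0.21 and the histamine receptor gene HRH1 at 1.21. The prostacyclin receptor gene PTGIR was at -4.04 ± 0.36, the bradykinin receptor gene BDKRB2 at -4.09 ± 0.62 and the delta opioid receptor gene OPRD1 at -2.52 ± 0.60. Among transduction channels TMC3 (4.65 ± 0.34), ANO3 (2.47 ± 0.32) and TRPV1 were higher, and TRPA1 and the acid-sensing channel gene ASIC3 (-1.40 ± 0.36) lower, 3 and 2 of 22 (5 and 4 adjusted over the list alone). These genes passed edgeR's adjusted threshold over all genes and were picked from lists fixed beforehand, after their values had been seen.

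Cluster 2, which could not be named, carried markers of several classes, among them TRPM8 and FOXP2, NTRK2, NTRK3 and SCN1A, and TH, GFRA2 and CDH9. Its neurons had a mean action potential duration of 2.02 ± 0.624 (SD, n = 8 animals) against 3.45 ± 0.590 in the other neurons of the same animals. Their 100 Hz value was 12.2 ± 4.42 against 5.57 ± 1.33 and their action potential threshold -51.4 ± 5.98 against -43.5 ± 1.45, each in the same direction in 8 of 8 animals. Of 46 parameters 0 passed by the exact sign-flip test, with 14 at an unadjusted p under 0.05. The smallest p possible with 8 animals is 0.00781, which 5 parameters reached (adjusted p = 0.0719), where 8 would have been enough for a pass. Peptidergic C-fibre-like neurons against all other neurons differed in 10 of 46 parameters, 8 higher and 2 lower, with an action potential threshold of -41.8 ± 2.13 against -45.4 ± 2.71 (exact sign-flip p = 0.00586, adjusted p = 0.0337, n = 10 animals). Cluster 6 had a macrophage score of 4.80 ± 0.916 (SD, n = 7 animals), the highest of the classes, and a neuron score of 6.57 ± 0.661 against 7.39 ± 0.173 in OSMR SST C-fibre-like cells.

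The ribosomal protein and oxidative phosphorylation lists lay higher at 3 than at 1 day, with only animals 2, 4 and 7 recorded at 3 days. Both calls were lost with an estimated correlation (adjusted p = 0.549 with an estimated correlation for each). A difference between runs of cell numbers is argued against, since with animal and run as the block the ribosomal protein median was 0.73 (fry p = 0.000497), and so is RNA from macrophages or cells of few genes, since without clusters 3 and 6 it was 0.76 (fry p = 7.51e-05). Another mix of classes at 3 days stays open, and so does a lower complexity of the libraries, which was not tested (a mean of 11400 genes per cell at 3 days and 13250 at 1 day). Within sums per animal, class and day the median was 0.49 with a fry p = 0.0448. The rule written beforehand, a median above 0.3 with a fry p under 0.05, was thus met. The median did not exceed 0.3 by 2 SE (SE of the list mean 0.25), a further requirement outside that rule, so the mix of classes is left open. The longer culture itself may raise these genes, which this design cannot separate from the choice of cells, and the median was 0.60, 0.59 and 0.71 without animal 2, 4 or 7.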
